A study of Mus musculus with 9 samples.

How the data were processed

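Messenger RNA was sequenced from 9 cultures of KPC mouse pancreatic cancer cells, 3 of each of 3 engineered lines. Per the labels, the replicates were biological, every culture had received doxycycline at 1 µg/ml for 48 h, and libraries were made from polyadenylated RNA with the NEBNext Ultra II Directional kit. The deposited table holds raw counts, as whole numbers per Ensembl gene with 1 column per sample. The authors' notes name the genome build GRCm39 and the programs FastQC 0.11.9, STAR 2.7.10a and DESeq2, and they do not state the order of steps, the annotation, the counting program or the strand setting. How reads that match several genes were counted was not stated either.

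The 56923 identifiers were matched to gene symbols of an annotation of the older GRCm38 build, which named 52073 of them and 12074 of the 12279 genes tested. Only symbols were taken from that annotation. Columns were assigned to groups by the sample titles, and no column was left unmatched. All 9 samples were used.

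Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with the filterByExpr function, which left 12279 of the 25499 genes with a count above 0 and 99.9% of all counts. Libraries were scaled with TMM factors, and 1 quasi-likelihood model was fitted to all 9 samples with a mean for each group (6 residual degrees of freedom, prior count 0.125). The comparisons were MYC RBRIIIMUT against MYC WT, MYC WT against shMYC and MYC RBRIIIMUT against shMYC. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The adjusted p-values given for genes are from edgeR. For members of a list the adjustment was also made over that list alone.

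Gene lists were written by hand before the data were examined, as were the groups, the comparisons, the alternative settings and the rule for naming genes. There were 32 lists with 785 entries (760 different genes), of which 4 had no match, and the 28 lists with at least 5 tested members were tested. The test was camera in limma 3.58.1 with the preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and it was repeated with the correlation estimated from the data. The other 4 lists hold markers of leukocytes, fibroblasts and stellate cells, endothelial cells, and pancreatic acinar and endocrine cells, and are reported as summed CPM. After the data had been seen, lists of NRF2 target genes and gastric foveolar genes were added for the closing section.

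The genes named are Myc, the 8 largest rises and 8 largest falls of each comparison, and up to 4 members of each list described. Largest changes were taken among called genes with a symbol, a mean of at least 1 CPM over the groups compared and no overlap between the replicates of the groups, which chance gives for 10% of genes with 3 against 3. List members were those with the smallest adjusted p. With 3 samples per group the smallest p of an exact permutation test is 0.1, so such a test was not used for single genes. Ratios of genes with 3 or fewer counts in a group are given with exact 95% intervals from the counts.

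The responses to the constructs were compared by the correlation of their log2 fold changes. Since both responses share the shMYC libraries, the correlation was set beside 20 simulations of counts without differences between groups. A common slope of the MYC RBRIIIMUT response on the MYC WT response was computed after subtracting the simulated covariance and variance, and departures of genes and lists from that slope were tested as a contrast of the same model.

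Total counts were 10926340 to 14458473 per sample, and the correlation of log CPM between replicates was 0.995 to 0.996. The biological coefficient of variation was 4.38%. The procedure was tested on simulated data at these depths, with 50 genes changed at each fold. For MYC RBRIIIMUT against MYC WT it recovered 56% of genes changed 1.25-fold, 80% at 1.5-fold, 88% at 2-fold and 98% at 4-fold, with 13 false calls among 12049 unchanged genes. For MYC WT against shMYC it recovered 50%, 74%, 90% and 100%, with 6 false calls, and for MYC RBRIIIMUT against shMYC 52%, 72%, 88% and 94%, with 10. A list with simulated changes was found by camera in each comparison, and a list without changes in none. Genes were simulated independently, with a single unchanged list per comparison. The simulation therefore cannot show how often lists of correlated genes are called falsely.

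The alternatives tried were median-of-ratios scaling, scaling by library size, no filter on low counts, a filter at a mean of 1 CPM, a block for the replicate number, the DESeq2 1.42.0 Wald test, a fit of only the groups compared, leaving out each sample in turn, and the estimated correlation for lists. After the data had been seen, the shMYC libraries were also divided between the comparisons in each of 6 ways, with 1 library for one construct and 2 for the other. Coordinates were left out because the annotation at hand was of another build. Isoforms and the share of construct transcripts were left out because the table holds 1 count per gene.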

Results

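Messenger RNA was sequenced in KPC cells, a mouse pancreatic cancer line derived from tumours with mutant Kras and Trp53. There were 9 samples in 3 groups of 3 biological replicates, and all had received doxycycline at 1 µg/ml for 48 h. The shMYC group carried inducible short hairpin RNAs against MYC and no MYC construct, and it served as the control. The MYC WT group carried the hairpins and an inducible wild-type MYC construct, and the MYC RBRIIIMUT group carried the hairpins and the RBRIIIMUT form of MYC. Total counts per sample ranged from 10926340 to 14458473, with 13071319 to 14458473 in MYC RBRIIIMUT, 10926340 to 12424128 in MYC WT and 11235208 to 13644818 in shMYC. Of 56923 genes in the table, 25499 had a count above 0 and 12279 were tested. Symbols stand for the Ensembl identifiers of the table, such as ENSMUSG00000022346 for Myc. Coordinates are not given, because the annotation at hand was of an older mouse build than the one named by the submitters. Levels are CPM, scaled with TMM factors and given as mean ± SD (n = 3 per group). Log2 fold changes are given ± SE. Where a gene list has a pair of adjusted p-values, the first is with the preset correlation between genes and the second with an estimated one. Counts of list members called were the same adjusted over the list alone, except where both counts are given.

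The groups separated on the first principal component, which held 62.5% of the variance, and the second held 8.55%. The 10 most abundant genes held a mean of 5.48% of counts in shMYC, 3.97% in MYC WT and 3.91% in MYC RBRIIIMUT. Mitochondrially encoded genes held 1.74% to 1.90% in shMYC, 1.39% to 1.71% in MYC WT and 1.38% to 1.51% in MYC RBRIIIMUT. In shMYC replicate 1 some transcripts stood apart from the other shMYC replicates. These transcripts were chosen after their values were seen. ENSMUSG00000119584 was at 8587 CPM against a mean of 2222 CPM in the other shMYC replicates, and Lars2, the mitochondrial leucyl-tRNA synthetase, was at 899 against 231 CPM. Relative to the same mean, ENSMUSG00002075795 was 5.15-fold, Gm15564 4.72-fold and Mir6236 3.56-fold higher. Apob, which encodes an apolipoprotein, was at 2534 against 1850.4 CPM. Ahnak was 1.42-fold, Lrp2 1.34-fold, Flnb 1.28-fold and Flna 1.19-fold higher. Whether these differences reflect the quality of the shMYC replicate 1 library was not tested. Without this library 7774 genes were called in place of 8054 for MYC WT against shMYC, 7185 in place of 7550 for MYC RBRIIIMUT against shMYC, and 1167 in place of 1070 for MYC RBRIIIMUT against MYC WT.

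Myc itself was measured first, since it was the gene targeted and re-expressed. Myc was at 68.7, 65.2 and 62.3 CPM in the shMYC replicates, at 110.5, 135 and 127 CPM in MYC WT, and at 129.5, 127 and 131 CPM in MYC RBRIIIMUT. The mean was 65.4 ± 3.19 CPM in shMYC, 124 ± 12.5 CPM in MYC WT and 129 ± 2.08 CPM in MYC RBRIIIMUT. Myc was 1.90-fold higher in MYC WT than in shMYC (log2 0.92 ± 0.06, adjusted p = 4.61e-17) and 1.97-fold higher in MYC RBRIIIMUT than in shMYC (log2 0.98 ± 0.06, adjusted p = 7.74e-18). No difference in Myc between the 2 construct groups passed the test (log2 0.05 ± 0.05, adjusted p = 0.63), and the sign turned without MYC WT replicate 1 (log2 -0.02). These counts do not separate transcripts of the endogenous gene from those of a construct, and the species of the construct's sequence was not stated.

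The comparison of MYC RBRIIIMUT with MYC WT addresses the study's main question, how the expression profile with the mutant differs from that with wild-type MYC. Cells with MYC RBRIIIMUT had higher levels of the matrix and TGF-beta response list than cells with MYC WT, with Sparc, a secreted matrix glycoprotein, at 109 ± 2.45 against 53.4 ± 2.03 CPM. Vcam1, an adhesion molecule of the NF-kappaB list, was at 65.7 ± 3.98 against 37.8 ± 1.74 CPM. The lists of MYC-activated core targets, ribosome biogenesis, nucleotide synthesis and the integrated stress response were lower, with Srm, spermidine synthase, at 208 ± 13.8 against 257 ± 2.72 CPM and Slc7a5, an amino acid transporter, at 261 ± 1.99 against 340 ± 6.96 CPM. Interferon-stimulated genes as a list did not pass the test. In all, 1070 genes passed the threshold, 621 higher and 449 lower in MYC RBRIIIMUT, which is 8.71% of those tested. The excess of higher genes depended on the scaling, with 564 higher and 574 lower under median-of-ratios scaling and 665 and 398 under library-size scaling. DESeq2, which changes the test along with the scaling, gave 472 and 461. Most differences were small, with a median absolute log2 fold change of 0.26 among the genes called, and 96 genes differed by 2-fold or more, 87 of them higher. Without MYC WT replicate 1 the count was 682. Of 28 gene lists 12 passed, 3 higher and 9 lower, and 5 passed with an estimated correlation as well.

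Among the 49 tested MYC-activated core targets, 16 were lower, 33 were not called and none was higher, and 26 were lower adjusted over the list alone. The median log2 fold change was -0.13 (adjusted p = 9.03e-16 and 0.0158). Utp20, a factor of small ribosomal subunit processing, was 0.772-fold (log2 -0.37 ± 0.05, adjusted p = 1.73e-06), and Srm was 0.810-fold (log2 -0.30 ± 0.04, adjusted p = 4.79e-06). Cad, which starts pyrimidine synthesis, was 0.829-fold and Polr1b, a subunit of RNA polymerase I, 0.797-fold. Of the 40 ribosome biogenesis factors 12 were lower, 28 were not called and none was higher, and 25 were lower adjusted over the list alone. Their median was -0.14 (adjusted p = 1.24e-15 and 0.0319). Rrp1b fell to 0.776-fold, Nol6 to 0.813-fold, Heatr1 to 0.818-fold and Noc2l to 0.844-fold, all nucleolar assembly factors. Of 26 nucleotide synthesis genes 6 were lower and 20 were not called, with 7 lower adjusted over the list alone, and the median was -0.07 (adjusted p = 0.00134 and 0.0353). Without MYC RBRIIIMUT replicate 1, MYC WT replicate 1 or MYC WT replicate 2 the number of core targets called lower was 10, and nucleotide synthesis had 3 without MYC RBRIIIMUT replicate 2 or MYC WT replicate 1. In that list the mitochondrial one-carbon enzymes Shmt2 and Mthfd2 were at 0.775-fold and 0.849-fold, and the purine enzyme Gart was at 0.848-fold.

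Genes of the integrated stress response, which are switched on by the transcription factor ATF4 and supply amino acids, were lower in MYC RBRIIIMUT than in MYC WT. Of 22 tested, 11 were lower, 11 were not called and none was higher, with 13 lower adjusted over the list alone, and the median was -0.21 (adjusted p = 1.17e-14 and 0.0103). Slc7a5, which carries large neutral amino acids, was at 0.767-fold (log2 -0.38 ± 0.04, adjusted p = 2.78e-09). Asns, asparagine synthetase, was at 300.0 ± 7.43 against 383 ± 15.6 CPM (log2 -0.35 ± 0.04, adjusted p = 2.89e-08). Slc7a11, the cystine transporter, was at 76.8 against 106 CPM (log2 -0.46 ± 0.06, adjusted p = 3.71e-07).

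Genes of the extracellular matrix and TGF-beta response were higher in MYC RBRIIIMUT than in MYC WT. Of 17 tested, 8 were higher, 9 were not called and none was lower, with 9 higher adjusted over the list alone, and the median was 0.34 (adjusted p = 3.95e-16 and 0.0103). Sparc was 2.05-fold higher (log2 1.03 ± 0.05, adjusted p = 4.64e-17), and its level in shMYC was 128 ± 4.42 CPM. Ccn2, a matricellular growth factor, was 1.53-fold higher (log2 0.61 ± 0.09, adjusted p = 7.36e-06), and Serpine1, a plasminogen activator inhibitor, was 1.38-fold higher (log2 0.47 ± 0.08, adjusted p = 1.33e-04). Thbs1, which encodes thrombospondin, was 8.91-fold higher (log2 3.16 ± 0.52, adjusted p = 3.84e-05), with 75 counts over the MYC RBRIIIMUT libraries and 7 over the MYC WT libraries. Markers of fibroblasts, the cells that make most matrix in tumours, summed to 0.977 ± 0.516 CPM in MYC RBRIIIMUT, 0.516 ± 0.171 CPM in MYC WT and 1.05 ± 0.380 CPM in shMYC, and none of the 15 passed the filter on low counts.

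The other genes with the largest rises were Nes at 6.05-fold, which encodes the intermediate filament nestin, the phosphodiesterase Pde3b at 4.89-fold, the collagen VI chains Col6a2 at 4.87-fold and Col6a1 at 3.76-fold, the small heat shock protein Cryab at 4.15-fold, the predicted gene Gm10800 at 3.61-fold and the kinesin Kif21b at 3.53-fold. Most of these were rare transcripts, with Nes at 1.75 ± 0.608 against 0.281 ± 0.187 CPM, while Cryab was at 5.70 ± 1.66 against 1.36 ± 0.0848 CPM. The largest falls were in Ppfibp2, which encodes a liprin, at 0.148-fold (log2 -2.76 ± 0.44, adjusted p = 2.30e-05) and in Ambp, the precursor of bikunin, at 0.243-fold (log2 -2.04 ± 0.32, adjusted p = 2.10e-05). They were followed by Morc4 at 0.364-fold, the sialyltransferase St6galnac3 at 0.396-fold, 5330417C22Rik at 0.408-fold, the hypoxia-inducible factor subunit Epas1 at 0.441-fold, the phosphodiesterase Pde4c at 0.497-fold and the ectoenzyme Enpp3 at 0.512-fold. The call for St6galnac3 was lost without MYC RBRIIIMUT replicate 1 (adjusted p = 0.0569) and without MYC WT replicate 2 (adjusted p = 0.0742). The call for 5330417C22Rik was lost without MYC RBRIIIMUT replicate 1 (adjusted p = 0.0659) or 3 (adjusted p = 0.229), without MYC WT replicate 1 (adjusted p = 0.232) or 3 (adjusted p = 0.103), and without shMYC replicate 2 (adjusted p = 0.0522) or 3 (adjusted p = 0.0525). It was also lost in a fit of only the groups compared (adjusted p = 0.0618).

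Innate immune genes were examined because the series title names innate immune signalling. The list of interferon-stimulated genes held 50, of which only 21 were tested, so its result does not cover the others. Of those 21, 1 was higher, 20 were not called and none was lower, with 3 higher adjusted over the list alone. The list's median log2 fold change was 0.14 and its test did not pass (adjusted p = 0.103 and 0.236). The list passed without MYC RBRIIIMUT replicate 2 (median 0.21, adjusted p = 0.0353) and with no filter on low counts (median 0.20, adjusted p = 0.0042). The gene called was Eif2ak2, the double-stranded RNA sensor PKR, at 60.1 ± 5.14 against 52.1 ± 1.47 CPM (log2 0.21 ± 0.06, adjusted p = 0.0342). Its call was lost without MYC RBRIIIMUT replicate 2 (adjusted p = 0.0717) or 3 (adjusted p = 0.253), without MYC WT replicate 1 (adjusted p = 0.0608), 2 (adjusted p = 0.137) or 3 (adjusted p = 0.0923), and with DESeq2 (adjusted p = 0.0841). Without MYC RBRIIIMUT replicate 1 another member of the list was called lower. Ddx58, the sensor RIG-I, was at 4.55 ± 0.681 against 2.96 ± 0.467 CPM and was not called (log2 0.62 ± 0.22, adjusted p = 0.0663), although it was without MYC RBRIIIMUT replicate 2 (adjusted p = 0.0479). Isg20, an exonuclease, was likewise not called (log2 0.25 ± 0.08, adjusted p = 0.0606) except without that library (adjusted p = 0.0373). The interferon-gamma response list had 6 of 20 genes tested, of which only Irgm1, an immunity-related GTPase, was higher (log2 0.32 ± 0.07, adjusted p = 0.00105). That list did not pass (median 0.24, adjusted p = 0.112) except without MYC RBRIIIMUT replicate 3 (adjusted p = 0.0259). Of 14 genes of MHC class I antigen presentation 2 were higher, namely the class I heavy chain H2-K1 at 1.44-fold (adjusted p = 3.00e-05) and the proteasome activator Psme1 at 1.22-fold (adjusted p = 0.00405), and the list did not pass (median 0.02, adjusted p = 0.381). Of 18 genes in the list of innate nucleic acid sensing Eif2ak2 was higher, the receptor Tlr4 was lower at 0.568-fold (adjusted p = 0.0134) and 16 were not called. Adjusted over the list alone 3 were higher and 1 was lower, and the list did not pass (median 0.07, adjusted p = 0.421). Tlr4 was written into this list but is a receptor for lipopolysaccharide, so its fall is not that of a nucleic acid sensor. The call for Tlr4 was lost without MYC RBRIIIMUT replicate 1 (adjusted p = 0.0575) and without MYC WT replicate 3 (adjusted p = 0.0556). None of the 8 genes for interferons and their receptors was called by edgeR or DESeq2, and none had an unadjusted p under 0.05 (list adjusted p = 0.757), and the list had a median near 0 whose sign differed between settings.

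**Figure D1:**
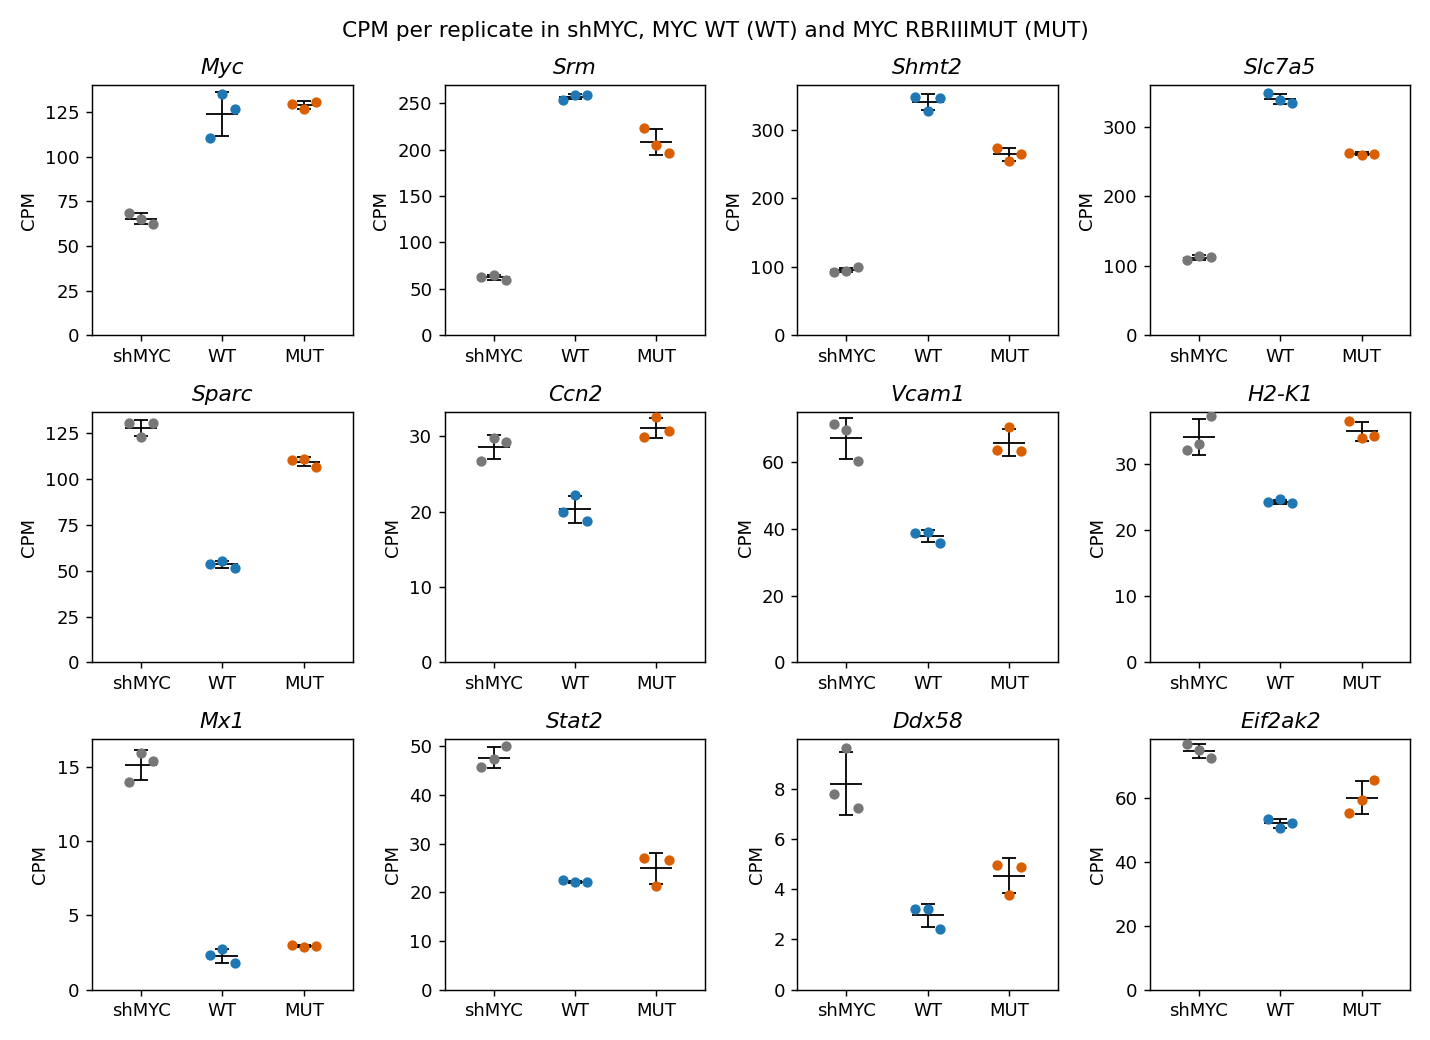
Levels (vertical axes, CPM, from 0) of 12 genes in each replicate of shMYC, MYC WT (WT) and MYC RBRIIIMUT (MUT), with bars for the mean and SD (n = 3). Sparc was at 53.4 CPM in MYC WT against 109 CPM in MYC RBRIIIMUT, while Mx1 was at 2.27 and 2.93 CPM in the construct groups and 15.1 CPM in shMYC.

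Among NF-kappaB target genes 7 were higher, 2 were lower and 16 of 25 were not called, with 8 higher and 4 lower adjusted over the list alone. The list passed with the preset correlation only (median 0.04, adjusted p = 0.0208 and 0.236). Its call was also lost without MYC RBRIIIMUT replicate 1 (adjusted p = 0.0692), without MYC WT replicate 1 (median -0.0054, adjusted p = 0.0884) and with no filter on low counts (adjusted p = 0.0844). Vcam1 was 1.74-fold higher (log2 0.80 ± 0.07, adjusted p = 1.08e-10), the chemokine Ccl20 was 1.37-fold higher (log2 0.45 ± 0.06, adjusted p = 1.87e-06) and Tnfaip2 was 1.51-fold higher (log2 0.60 ± 0.11, adjusted p = 1.13e-04). Of 23 lysosome and autophagy genes 5 were higher, 18 were not called and none was lower (median 0.09, adjusted p = 0.0199 and 0.236), and the list's call was lost without MYC RBRIIIMUT replicate 1 (adjusted p = 0.0678). Lysosome genes called higher were 1 without MYC RBRIIIMUT replicate 1 or MYC WT replicate 2, 2 without MYC WT replicate 1 and 3 without MYC WT replicate 3, and NF-kappaB targets called higher were 4 without MYC RBRIIIMUT replicate 2 or MYC WT replicate 3. The lysosomal protease Ctsl was 1.22-fold higher (adjusted p = 5.05e-04).

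Further lists were lower with the preset correlation only. Of 39 cytosolic ribosomal proteins 3 were lower and 36 were not called, with 7 lower adjusted over the list alone (median -0.06, adjusted p = 0.0017 and 0.236). Each of those 3 calls was lost without at least 1 library, for Rpl10a without MYC RBRIIIMUT replicate 2 (adjusted p = 0.187) or 3 (adjusted p = 0.12) and MYC WT replicate 2 (adjusted p = 0.0731) or 3 (adjusted p = 0.198), and for Rpl32 without MYC RBRIIIMUT replicate 3 (adjusted p = 0.101) and MYC WT replicate 1 (adjusted p = 0.116) or 3 (adjusted p = 0.0739). Rps2 lost its call without MYC RBRIIIMUT replicate 2 (adjusted p = 0.148) or 3 (adjusted p = 0.202), MYC WT replicate 1 (adjusted p = 0.0995) or 3 (adjusted p = 0.218), and shMYC replicate 2 (adjusted p = 0.0538) or 3 (adjusted p = 0.0519). It also lost its call with library-size scaling (adjusted p = 0.0644). The number of these genes called ran from 0 (without MYC RBRIIIMUT replicate 3 or MYC WT replicate 3) to 9 (without MYC RBRIIIMUT replicate 1), with 1 without MYC RBRIIIMUT replicate 2 or MYC WT replicate 1 and 7 without shMYC replicate 1. Of 18 glycolysis genes 4 were lower, 14 were not called and 7 were lower adjusted over the list alone (median -0.07, adjusted p = 0.00144 and 0.236), and the pyruvate dehydrogenase kinase Pdk1 was at 0.683-fold (adjusted p = 1.67e-04), and 2 were lower without MYC RBRIIIMUT replicate 2 or MYC WT replicate 3. Of 26 genes for the mitochondrial ribosome and import 3 were lower, and 23 were not called (median -0.09, adjusted p = 0.00144 and 0.087). None of these calls was kept without MYC RBRIIIMUT replicate 1, MYC RBRIIIMUT replicate 2, MYC WT replicate 2 or MYC WT replicate 3, and 1 was kept without MYC RBRIIIMUT replicate 3. Of 24 genes for RNA modification and double-stranded RNA control 3 were lower, and 21 were not called (median -0.05, adjusted p = 0.0125 and 0.087), and the RNA cytosine methyltransferase Nsun2 was at 0.867-fold (adjusted p = 2.85e-04), while 1 was lower without MYC RBRIIIMUT replicate 1 or 2 or MYC WT replicate 2 or 3. Of 15 heat shock chaperones 3 were lower, and 12 were not called (median -0.04, adjusted p = 0.0229 and 0.115), and the co-chaperone Fkbp4 was at 0.861-fold (adjusted p = 5.40e-05).

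The remaining lists did not pass for MYC RBRIIIMUT against MYC WT. None of 30 genes of S phase and DNA replication was called by edgeR or by DESeq2, and 3 had an unadjusted p under 0.05 (list adjusted p = 0.779, with a median near 0 whose sign differed between settings). None of 19 genes of cholesterol synthesis was called by edgeR, while DESeq2 called 1 and 6 had an unadjusted p under 0.05 (list adjusted p = 0.757). Neither list had calls adjusted over the list alone. None of 23 genes of the RNA exosome and its targeting complexes was called by edgeR, or by DESeq2, and 5 had an unadjusted p under 0.05 (median -0.06, adjusted p = 0.0529), and that list passed with median-of-ratios scaling (adjusted p = 0.0393) and with no filter on low counts (adjusted p = 0.0042). It also passed without MYC RBRIIIMUT replicate 3 (adjusted p = 0.0488), MYC WT replicate 1 (adjusted p = 0.0456), MYC WT replicate 3 (adjusted p = 0.0399) or shMYC replicate 2 (adjusted p = 0.0474). Of 30 mitosis genes 1 was higher and 3 were lower (adjusted p = 0.267), and of 16 p53 target genes 2 were higher and 1 was lower (adjusted p = 0.946, with a median near 0 whose sign differed between settings), with the same counts adjusted over the list alone. Mitosis genes called higher and lower were 0 and 0 without MYC RBRIIIMUT replicate 2, 1 and 1 without MYC RBRIIIMUT replicate 3, 0 and 1 without MYC WT replicate 1 or 3, and 1 and 0 without MYC WT replicate 2. The p53 list had 1 called higher without MYC RBRIIIMUT replicate 2 or MYC WT replicate 3. The polo-like kinase Plk2, in the p53 list, was 1.56-fold higher (adjusted p = 1.55e-05). Of 18 genes of the unfolded protein response 1 was higher (adjusted p = 0.757, with a median near 0 whose sign differed between settings). Of 17 hypoxia and angiogenesis genes 2 were higher and 3 were lower, against 4 and 4 adjusted over the list alone (adjusted p = 0.595, with a median near 0 whose sign differed between settings). Of 18 MYC-repressed genes 3 were higher and 1 was lower, against 5 and 1 adjusted over the list alone (adjusted p = 0.133), and of 10 MYC network transcription factors 1 was lower, against 2 adjusted over the list alone (adjusted p = 0.16). The network factor was Mxi1, whose call was lost without any 1 of the 6 construct libraries (adjusted p = 0.0624 to 0.129), with no filter on low counts (adjusted p = 0.0599) and with DESeq2 (adjusted p = 0.0628). MYC-repressed genes had 1 higher without MYC RBRIIIMUT replicate 1 or MYC WT replicate 1. Of 14 epithelial identity genes 3 were higher and 1 was lower, against 4 and 1 adjusted over the list alone (adjusted p = 0.163), and the keratins Krt18 and Krt8 were 1.20-fold (adjusted p = 1.40e-07) and 1.11-fold higher (adjusted p = 3.50e-04). The epithelial gene called lower lost its call without MYC RBRIIIMUT replicate 1 or 2 and MYC WT replicate 1 or 3. Hypoxia genes called higher and lower were 0 and 3 without MYC RBRIIIMUT replicate 1, 1 and 2 without MYC RBRIIIMUT replicate 2, 1 and 3 without MYC WT replicate 2, and 1 and 1 without MYC WT replicate 3. Of 5 mesenchymal identity genes the receptor kinase Axl was higher at 1.24-fold (adjusted p = 8.62e-07), and adjusted over the list alone 1 was higher and 1 lower (adjusted p = 0.18), while 1 was lower without MYC RBRIIIMUT replicate 2. Without a single library 1 gene was called for S phase (MYC WT replicate 1), cholesterol synthesis (MYC RBRIIIMUT replicate 2, MYC WT replicate 1 or MYC WT replicate 3) and the RNA exosome (MYC RBRIIIMUT replicate 1 or MYC WT replicate 2). Markers of other cell types were mostly under the filter, with 3 of 20 leukocyte, 2 of 11 endothelial and 1 of 18 pancreatic acinar and endocrine markers tested. Leukocyte markers summed to 73.8 ± 1.47 CPM in MYC RBRIIIMUT, 78.3 ± 0.839 CPM in MYC WT and 81.1 ± 8.15 CPM in shMYC. Most of that sum was Cd14, which was not called between the construct groups (adjusted p = 0.894) and was lower in both than in shMYC (log2 -0.35 for MYC WT and -0.32 for MYC RBRIIIMUT). Lcp1, an actin-bundling protein in the same set, was at 16.1 ± 2.64 CPM in MYC RBRIIIMUT, 22.4 ± 1.26 CPM in MYC WT and 9.59 ± 1.04 CPM in shMYC. It was lower in MYC RBRIIIMUT than in MYC WT (log2 -0.48 ± 0.11, adjusted p = 0.00414) and higher in both than in shMYC, and the third tested marker, Cd68, was not called. Endothelial markers summed to 5.12 ± 0.900, 4.69 ± 0.402 and 5.50 ± 0.693 CPM, and acinar and endocrine markers to 4.12 ± 0.439, 3.49 ± 0.240 and 2.63 ± 0.502 CPM, in the same order. Of these only Cela1, an acinar elastase, was called, higher in MYC RBRIIIMUT than in shMYC (log2 0.97 ± 0.28, adjusted p = 0.00325). For MYC WT against shMYC it was called adjusted over its list alone, without MYC WT replicate 3 (adjusted p = 0.0391) and without shMYC replicate 3 (adjusted p = 0.0176), but not otherwise (log2 0.65 ± 0.30, adjusted p = 0.0531). Each group was a different engineered line, so differences between groups include any difference between the lines.

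The comparison of MYC WT with shMYC asks what wild-type MYC changes in cells whose own MYC is targeted. With MYC WT, the lists for ribosomes, nucleotide synthesis, DNA replication and mitosis were higher, and those for epithelial identity and lysosomes were lower. Ncl, the nucleolar protein nucleolin, rose from 701 ± 55.6 to 2808 ± 98.5 CPM (adjusted p = 2.79e-32). Mx1, an interferon-induced antiviral GTPase, fell from 15.1 ± 1.01 to 2.27 ± 0.478 CPM (0.150-fold, log2 -2.73 ± 0.18, adjusted p = 2.07e-16). In all, 8054 genes passed the threshold, 4026 higher and 4028 lower, which is 65.6% of those tested. Levels are relative within each library, so this near-even split does not show that total mRNA per cell was equal. A fold of 2 or more was seen in 1416 of them, 520 higher and 896 lower, and the median absolute log2 fold change among the genes called was 0.53. Of 28 gene lists 21 passed, 12 higher and 9 lower, and 13 passed with an estimated correlation as well.

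Of 49 MYC-activated core targets 48 rose and 1 fell in MYC WT (median 1.40, adjusted p = 1.34e-67 and 2.06e-04). Besides Ncl, the nucleolar chaperone Npm1 rose 3.06-fold, the mitochondrial chaperonin Hspd1 rose 3.25-fold and the nucleolar factor Mybbp1a rose 3.17-fold. All 40 ribosome biogenesis factors rose (median 1.16, adjusted p = 4.79e-48 and 8.05e-04), among them Rrp1b at 3.98-fold and Noc2l at 3.74-fold. All 39 cytosolic ribosomal proteins rose (median 0.60, adjusted p = 1.63e-19 and 0.00846). Of 26 nucleotide synthesis genes 25 rose and none fell (median 0.87, adjusted p = 4.46e-23 and 3.96e-04), with Shmt2 at 3.58-fold and the purine enzyme Atic at 2.67-fold. Of 26 genes for the mitochondrial ribosome and import 25 rose and none fell (median 0.75, adjusted p = 6.99e-09 and 0.00846).

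Genes of the cell cycle and of RNA decay also rose with MYC WT. Of 30 genes of S phase and DNA replication 27 rose and 1 fell (median 0.66, adjusted p = 9.32e-13 and 0.00112), and the replicative helicase subunit Mcm3 rose 2.15-fold. All 30 mitosis genes rose (median 0.59, adjusted p = 7.04e-14 and 0.00854), and the cyclin Ccna2 rose 1.78-fold. Of 23 genes of the RNA exosome, the complex that degrades nuclear RNA, and its targeting complexes 17 rose and 3 fell (median 0.59, adjusted p = 4.51e-05 and 0.00846), with the exosome subunits Dis3 at 2.22-fold and Exosc2 at 2.23-fold. Of 24 genes of RNA modification and double-stranded RNA control 20 rose and 1 fell (median 0.52, adjusted p = 2.71e-06 and 0.00846), with Nsun2 at 2.46-fold and the helicase Dhx9 at 1.57-fold. Of 22 genes of the integrated stress response 15 rose and 4 fell (median 0.72, adjusted p = 2.26e-08 and 0.00846), with Slc7a5 at 3.05-fold. Of 15 heat shock chaperones 10 rose and 1 fell (median 0.55, adjusted p = 1.42e-06 and 0.00846), and Hsp90ab1 rose 2.05-fold. Of 18 glycolysis genes 11 rose and 2 fell (median 0.26, adjusted p = 0.00851 and 0.263), with the hexokinase Hk2 at 2.23-fold.

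Innate immune lists were lower in MYC WT than in shMYC with the preset correlation only. Of 21 interferon-stimulated genes 16 fell, 3 rose and 2 were not called (median -0.46, adjusted p = 0.00394 and 0.0662). Besides Mx1, Samd9l, an antiviral factor, fell to 0.549-fold (adjusted p = 2.61e-19), Stat2, a transducer of interferon signals, to 0.465-fold (adjusted p = 4.33e-14), and Oasl1 to 0.588-fold (adjusted p = 4.71e-12). Of 14 genes of MHC class I antigen presentation 9 fell and 3 rose (median -0.36, adjusted p = 0.0355 and 0.088). The class I molecule H2-T23 fell to 0.415-fold and the peptide loading factor Tapbp to 0.533-fold, while the immunoproteasome subunit Psmb10 rose 1.88-fold. Of 25 NF-kappaB target genes 15 fell and 6 rose (median -0.41, adjusted p = 0.0152 and 0.179), with Ccl20 at 0.403-fold. The list of 8 interferons and their receptors had 7 members that fell and none that rose, but did not pass (median -0.21, adjusted p = 0.0639), except without MYC WT replicate 1 (adjusted p = 0.0454) and with no filter on low counts (adjusted p = 0.00257). Neither the 6 interferon-gamma response genes, of which 3 fell (adjusted p = 0.26), nor the 18 genes of innate nucleic acid sensing, of which 7 fell and 4 rose (adjusted p = 0.16), passed as lists, and their counts were the same adjusted over the list alone.

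The lists for epithelial identity, lysosomes and, with the preset correlation only, the matrix were lower with MYC WT. Of 14 epithelial identity genes 12 fell and none rose (median -0.56, adjusted p = 1.66e-05 and 0.00846), with Krt8 at 0.534-fold and Krt19 at 0.521-fold. Of 23 lysosome and autophagy genes 18 fell and 1 rose (median -0.58, adjusted p = 2.45e-08 and 0.0169), with the sialidase Neu1 at 0.505-fold and the protease Ctsd at 0.479-fold. Of 17 matrix and TGF-beta response genes 13 fell and none rose (median -0.66, adjusted p = 6.49e-04 and 0.0733), with Sparc at 0.417-fold and the membrane protease Mmp14 at 0.541-fold. Of 18 MYC-repressed genes 11 fell and 3 rose (median -0.44, adjusted p = 0.0215 and 0.0698), with Sesn3 at 0.498-fold and Txnip at 0.465-fold. Of 18 genes of the unfolded protein response 10 fell and 2 rose (median -0.25, adjusted p = 0.0391 and 0.311), and the call was lost without shMYC replicate 1 (adjusted p = 0.0583). Of 19 cholesterol synthesis genes 13 fell and 2 rose (median -0.17, adjusted p = 0.0391 and 0.353), and the call was lost without MYC WT replicate 2 (adjusted p = 0.0596) or shMYC replicate 3 (adjusted p = 0.0651). The other lists that did not pass had members moving both ways, with the same counts adjusted over the list alone. They were the p53 targets with 4 rises and 6 falls of 16 (adjusted p = 0.555, with a median of 0.03 while the mean was -0.20 and the test pointed down), hypoxia and angiogenesis with 5 and 5 of 17 (adjusted p = 0.769, with a median near 0 whose sign differed between settings, library-size scaling among them), and mesenchymal identity with 1 and 4 of 5 (adjusted p = 0.555). They also included the MYC network factors with 7 rises and 2 falls of 10 (adjusted p = 0.586), where MYC's partner Max rose 1.54-fold and Mxd1, an antagonist of MYC, fell to 0.492-fold.

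The largest rises in MYC WT over shMYC were in Slc19a1, the reduced folate carrier, at 48.8 ± 1.54 against 8.37 ± 0.437 CPM (5.84-fold, log2 2.55 ± 0.10, adjusted p = 6.42e-24), the nuclear pore protein Nup210 at 5.27-fold, the nucleoside transporter Slc29a2 at 5.04-fold, the kinase Dyrk3 at 4.96-fold, Ltbp4 at 4.82-fold, Cdca7 at 4.75-fold, Morc4 at 4.54-fold and the deoxycytidylate deaminase Dctd at 4.52-fold. The largest falls were in Cdh6, a cadherin, with 2 counts over the MYC WT libraries and 96 over the shMYC libraries, which gives a level 44.9-fold higher in shMYC (exact 95% counting interval 12.1 to 376), and in Thbs1 at 0.0534-fold, from 7 and 148 counts. Then came the calcium channel subunit Cacna2d4 at 0.0554-fold, from 4 and 84 counts, the calpains Capn13 at 0.0694-fold and Capn9 at 0.0947-fold, the surface antigen Psca at 0.0810-fold (24.3 ± 0.424 CPM in shMYC and 1.96 ± 0.410 CPM in MYC WT), Cryab at 0.0948-fold and the gastrokine Gkn2 at 0.0956-fold.

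The comparison of MYC RBRIIIMUT with shMYC asks what the mutant form changes against the same control. Growth lists that rose with wild-type MYC also rose with the mutant, with Npm1 at 2047 ± 19.0 against 688 ± 18.2 CPM (2.97-fold, log2 1.57 ± 0.03, adjusted p = 1.63e-31) and Ncl at 3.62-fold. Mx1 was at 2.93 ± 0.0795 against 15.1 ± 1.01 CPM (0.194-fold, log2 -2.36 ± 0.17, adjusted p = 2.30e-15). In all, 7550 genes passed the threshold, 3842 higher and 3708 lower, which is 61.5% of those tested. A fold of 2 or more was seen in 945 of them, 367 higher and 578 lower, and the median absolute log2 fold change among the genes called was 0.47. As for MYC WT, 21 of 28 gene lists passed, 12 higher and 9 lower, and 13 passed with an estimated correlation as well.

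Of 49 MYC-activated core targets 48 rose and 1 fell in MYC RBRIIIMUT (median 1.26, adjusted p = 2.53e-68 and 2.20e-04), with Mybbp1a at 3.05-fold and Hspd1 at 2.81-fold. Of 40 ribosome biogenesis factors 39 rose and none fell (median 1.04, adjusted p = 2.40e-46 and 8.66e-04), with Noc2l at 3.15-fold and Rrs1 at 3.30-fold. All 39 cytosolic ribosomal proteins rose (median 0.57), as did 25 of 26 nucleotide synthesis genes (median 0.84), 23 of 26 genes for the mitochondrial ribosome and import (median 0.64), all 30 mitosis genes (median 0.59), 19 of 24 genes for RNA modification and double-stranded RNA control (median 0.50, with 1 that fell) and 10 of 15 heat shock chaperones (median 0.60, with 1 that fell). The counts for these lists were the same adjusted over the list alone, and the highest adjusted p among them was 1.91e-08 for the first 4 and 5.85e-06 for the others, against at most 0.00847 with an estimated correlation. Shmt1, a one-carbon enzyme of the nucleotide list, rose 2.99-fold, and the cyclin Ccnb1 rose 1.84-fold. Of 30 genes of S phase and DNA replication 27 rose and none fell, against 27 and 1 adjusted over the list alone (median 0.69, adjusted p = 6.27e-16 and 7.67e-04), with Mcm3 at 2.17-fold. Of 23 genes of the RNA exosome and its targeting complexes 19 rose and 3 fell (median 0.51, adjusted p = 5.33e-05 and 0.00884), with Dis3 at 2.22-fold. Of 22 genes of the integrated stress response 14 rose and 5 fell (median 0.50, adjusted p = 2.64e-05 and 0.0237), with Slc7a5 at 2.34-fold. Of 18 glycolysis genes 11 rose and 3 fell (median 0.17, adjusted p = 0.0401 and 0.376), and the call was lost without MYC RBRIIIMUT replicate 1 (adjusted p = 0.0576) and with the stricter filter on low counts (adjusted p = 0.0537).

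Innate immune lists were lower in MYC RBRIIIMUT than in shMYC, again with the preset correlation only. Of 21 interferon-stimulated genes 15 fell and 3 rose, against 16 and 3 adjusted over the list alone (median -0.43, adjusted p = 0.00571 and 0.0677). Samd9l fell to 0.567-fold (adjusted p = 1.34e-18), Stat2 to 0.524-fold (adjusted p = 2.16e-12) and the secreted glycoprotein Lgals3bp to 0.779-fold (adjusted p = 1.39e-10). Of 14 genes of MHC class I antigen presentation 8 fell and 3 rose (median -0.21, adjusted p = 0.0358 and 0.0912), with H2-T23 at 0.421-fold. Of 25 NF-kappaB target genes 12 fell and 3 rose (median -0.23, adjusted p = 0.0381 and 0.277), and the call was lost without MYC RBRIIIMUT replicate 3 (adjusted p = 0.0551). Vcam1, in that list, was at 0.979-fold and was not called (adjusted p = 0.701). Of 8 genes for interferons and their receptors 7 fell and none rose (median -0.22, adjusted p = 0.0452 and 0.152), among them the kinase Tyk2 at 0.606-fold. That list's call was lost without MYC RBRIIIMUT replicate 3 (adjusted p = 0.0516), shMYC replicate 2 (adjusted p = 0.0536) or shMYC replicate 3 (adjusted p = 0.0506), and with the stricter filter (adjusted p = 0.0507). Of 6 interferon-gamma response genes 3 fell (adjusted p = 0.458), and of 18 genes of innate nucleic acid sensing 8 fell and 3 rose (adjusted p = 0.179), and neither list passed.

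Of 14 epithelial identity genes 12 fell and none rose in MYC RBRIIIMUT (median -0.52, adjusted p = 9.18e-06 and 0.00847), with Krt8 at 0.595-fold. Of 23 lysosome and autophagy genes 18 fell and 2 rose (median -0.53, adjusted p = 2.14e-08 and 0.0208). Of 18 MYC-repressed genes 10 fell and 1 rose (median -0.22, adjusted p = 0.0331 and 0.0852), of 18 genes of the unfolded protein response 10 fell and none rose (median -0.22, adjusted p = 0.0329 and 0.294), and of 19 cholesterol synthesis genes 12 fell and 1 rose (median -0.17, adjusted p = 0.0329 and 0.325), the same adjusted over the list alone. Of 17 matrix and TGF-beta response genes 7 fell and none rose, and the list did not pass (median -0.13, adjusted p = 0.116), with Sparc at 0.855-fold (adjusted p = 1.14e-04). The p53 targets (3 rises and 6 falls, adjusted p = 0.494), hypoxia and angiogenesis (5 and 5, adjusted p = 0.645), mesenchymal identity (1 and 1, adjusted p = 0.799) and the MYC network factors (7 and 2, adjusted p = 0.846) did not pass either, and their counts were the same adjusted over the list alone.

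The largest rises in MYC RBRIIIMUT over shMYC included Slc19a1 at 4.75-fold (log2 2.25 ± 0.10, adjusted p = 7.28e-22), Nup210 at 4.42-fold, Dyrk3 at 4.28-fold, Mir17hg, the host transcript of a growth-promoting microRNA cluster, at 4.16-fold, and Dctd at 4.12-fold. They also included Hspd1-ps3 at 4.98-fold, Gm6477 at 4.76-fold and Gm13577 at 4.28-fold, the first of which is named as a pseudogene of Hspd1, and how reads shared between related genes were counted was not stated. The largest falls were in Mcf2l, a guanine nucleotide exchange factor, at 0.0931-fold (log2 -3.43 ± 0.45, adjusted p = 1.53e-08), the histone gene Hist2h3c2 at 0.0976-fold, the galectin Lgals12 at 0.103-fold, Rab33a at 0.119-fold, Rep15 at 0.120-fold, 5330417C22Rik at 0.130-fold, the lipid droplet protein Plin4 at 0.158-fold (28.1 ± 0.474 CPM in shMYC and 4.44 ± 0.850 CPM in MYC RBRIIIMUT) and Fer1l4 at 0.159-fold. Hist2h3c2, Rab33a and Rep15 rested on 8, 10 and 9 counts over the MYC RBRIIIMUT libraries.

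**Figure D2:**
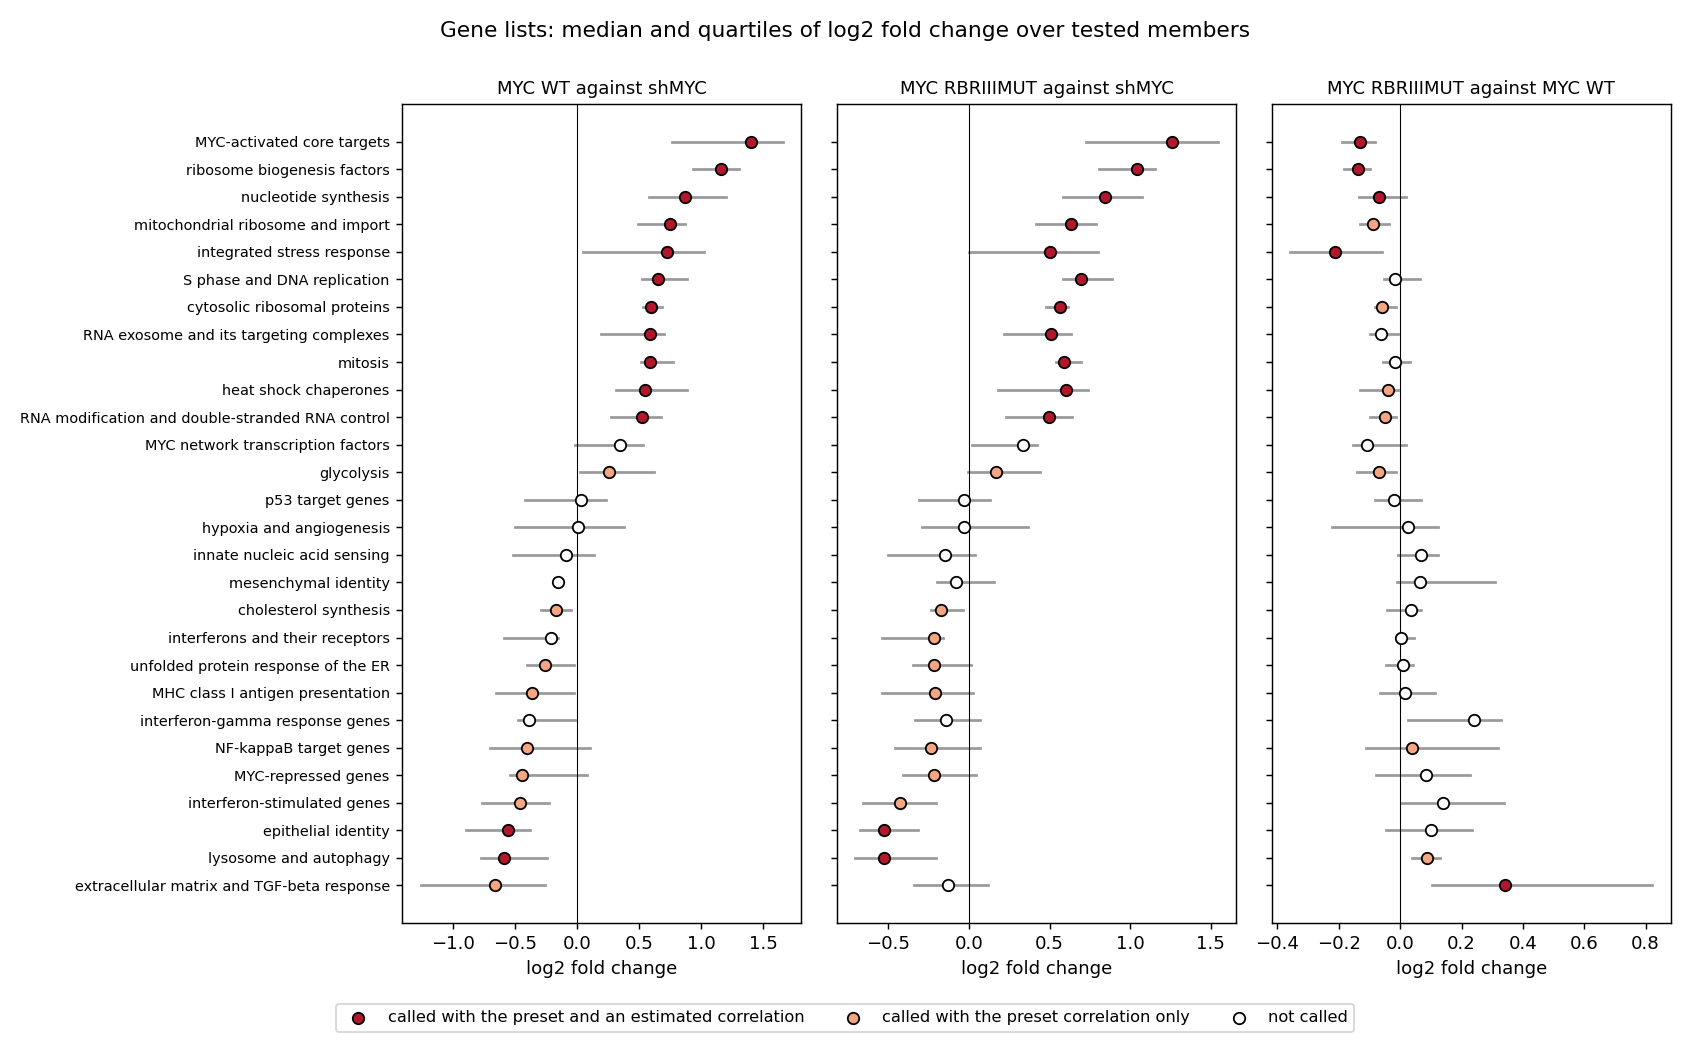
Median (points) and quartiles (lines) of the log2 fold change (horizontal axes, scaled separately) over the tested members of each of 28 gene lists in the 3 comparisons, with the fill giving whether the list passed the test. MYC-activated core targets sat at 1.40 and 1.26 against shMYC and at -0.13 for MYC RBRIIIMUT against MYC WT, while matrix and TGF-beta response genes sat at -0.66, -0.13 and 0.34.

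The responses to the 2 constructs were then compared gene by gene over the 12279 genes tested. Genes that rose or fell with MYC WT mostly did so with MYC RBRIIIMUT, with 3539 genes higher in both against shMYC, where independent lists of these sizes would share 1260, and 3349 lower in both, where independent lists would share 1216. Only 8 genes were called in opposite directions, where independent lists would give 2476. The correlation of the log2 fold changes across genes was 0.899, and genes are not independent replicates. Both comparisons share the shMYC libraries, so 20 simulations with unchanged groups and shared controls were run. These gave a mean correlation of 0.505 (0.484 to 0.521) and a mean of 0.05 genes called higher in both. Unchanged groups give almost no calls, so that overlap was bound to be small and says little about the observed one. The covariance was 0.358, against 0.0176 in the simulations, a difference of 0.341. With the shMYC libraries divided so that the comparisons shared none, a test chosen after the data were seen, the 6 divisions gave correlations of 0.761 to 0.794 and covariances of 0.335 to 0.342. They gave 2877 to 3022 genes higher in both, 2585 to 2759 lower in both and 6 to 14 in opposite directions.

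The response with MYC RBRIIIMUT was smaller, with a common slope of 0.796 on the response with MYC WT after the simulated covariance and variance were removed. No standard error was computed for this slope, and the tests of departure from it take it as fixed. Of the 621 genes higher in MYC RBRIIIMUT than in MYC WT, 549 were lower in MYC WT than in shMYC (204 for independent lists), and of the 449 lower genes 375 were higher in MYC WT than in shMYC (147 for independent lists). Both lists use the MYC WT libraries, and the correlation of the 2 sets of fold changes was -0.52, against -0.51 in the simulations. Their covariance was -0.105, against -0.0179 in the simulations (-0.0191 to -0.0166). No simulation had more than 1 gene in either overlap, but groups simulated without differences give almost no calls. That count cannot show how much of the overlaps comes from the shared MYC WT libraries. Compared with the common slope, 898 genes departed, 576 higher and 322 lower in MYC RBRIIIMUT. Lists departed upward for MYC-activated core targets (median departure 0.14, adjusted p = 0.0149 with an estimated correlation), nucleotide synthesis (0.13, adjusted p = 0.00775), S phase and DNA replication (0.12, adjusted p = 0.00682) and the matrix and TGF-beta response (0.27, adjusted p = 0.0166), all with the estimated correlation. Ribosome biogenesis factors (0.10), cytosolic ribosomal proteins (0.07) and mitosis (0.11) departed upward with the preset correlation only. The integrated stress response (-0.11, adjusted p = 0.00155 and 0.106), epithelial identity (-0.04, adjusted p = 0.041 and 0.136) and lysosome and autophagy (-0.06, adjusted p = 0.0485 and 0.35) departed downward, also with the preset correlation only. Relative to that slope the first 3 lists named kept more of their rise, while matrix genes kept less of their fall. MYC RBRIIIMUT lay outside the range of the other groups, with a call against each in the same direction, for 131 genes, 62 higher and 69 lower. Examples chosen after their values were seen were Lamb1, a laminin chain, 1.67 higher than MYC WT and 0.21 higher than shMYC on the log2 scale, and Anks6, 2.84 and 1.53 higher. Anks6 did not meet the rule on level and replicate overlap by which the largest rises were named. The receptor Tlr4 was lower than in both, at -0.82 and -0.64.

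**Figure D3:**
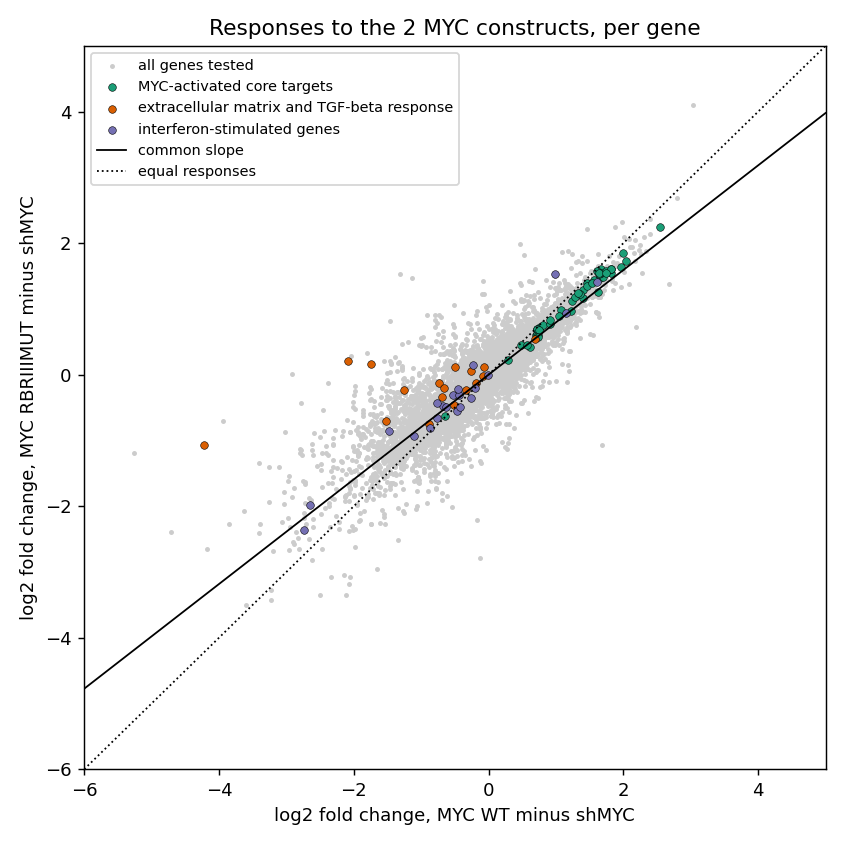
Log2 fold change of each of 12279 genes in MYC RBRIIIMUT minus shMYC (vertical axis) against MYC WT minus shMYC (horizontal axis), with the members of 3 lists in colour, the common slope of 0.796 as a solid line and equal responses as a dotted line. The correlation across genes was 0.899, and matrix and TGF-beta response genes lie above the solid line with a median departure of 0.27.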

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

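Of 1260 list results under the alternatives 1211 stayed on their side of the threshold, 37 lost their call and 12 gained a call, and of 6262 results for named genes 6078 did, 155 lost their call and 29 gained a call. List medians changed sign in 19 results, 18 of them called under neither setting and 1 for NF-kappaB target genes in MYC RBRIIIMUT against MYC WT, which lost its call without MYC WT replicate 1 (median -0.0054). Named genes changed sign in 15 results, called under neither setting. For MYC RBRIIIMUT against MYC WT the number of genes called ran from 682 (without MYC WT replicate 1) to 1167 (without shMYC replicate 1) when single samples were left out, and from 915 to 1138 under the other settings. Leaving out any other construct library gave 749 to 917 genes. Whether 682 lies beyond the spread that the lower number of samples gives was not tested. With median-of-ratios scaling 1138 genes were called, 564 higher and 574 lower, and 1013 of the 1070 were shared. DESeq2 called 933, of which 894 were shared, all in the same direction. For MYC WT against shMYC leaving out samples gave 7619 to 8160 genes, and for MYC RBRIIIMUT against shMYC 7014 to 7620. No scaling moved the median of all genes by over 0.1 on the log2 scale. With an estimated correlation 5 lists passed for MYC RBRIIIMUT against MYC WT, 13 for MYC WT against shMYC and 13 for MYC RBRIIIMUT against shMYC. Why fewer lists passed with that setting was not tested. The median of interferon-stimulated genes for MYC RBRIIIMUT against MYC WT was 0.201 with no filter on low counts, where the list passed (adjusted p = 0.0042), and 0.133 to 0.206 when samples were left out, where it passed without MYC RBRIIIMUT replicate 2 alone (adjusted p = 0.0353). The cause of these gains was not tested. The median of MYC-activated core targets was -0.138 to -0.124 when samples were left out and -0.144 to -0.123 under the other settings. The correlation of the responses was 0.858 (without MYC WT replicate 2) to 0.898 when samples were left out (jackknife SE 0.0368) and 0.922 with the filter at a mean of 1 CPM. With the shMYC libraries divided between the comparisons, chosen after the data were seen, the correlation moved to 0.791, 0.794 and 0.784 (only replicate 1, 2 or 3 with MYC WT) and to 0.779, 0.781 and 0.761 (only replicate 1, 2 or 3 with MYC RBRIIIMUT), with no shared library and fewer controls per comparison. Against shMYC the smaller of a list's counts of rises and falls moved by at most 2 genes when samples were left out. Replicate numbers did not pair the samples, as residuals of samples with the same number correlated at -0.0742 to 0.00787 and of those with other numbers at -0.0354 to 0.0853, and the block for replicate number gave 915, 7944 and 7422 genes. For MYC RBRIIIMUT against MYC WT the block ended the calls of 11 named genes, among them Eif2ak2 (adjusted p = 0.0575), 5330417C22Rik (0.0668), Rps2 (0.0613) and Rpl10a (0.0508), and the RNA exosome list passed (0.0491). At these depths 50% to 56% of the smallest simulated changes were recovered, so a missing call does not exclude a small change.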

Other observations

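The tests on Myc mRNA, fibroblasts and differences between the lines were chosen after the results were seen. So were the genes that led to the NRF2 and gastric lists.

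Genes that set MYC RBRIIIMUT apart from both other groups were chosen after their values were seen. Ambp, the bikunin precursor, was at -2.04 against MYC WT and -2.22 against shMYC on the log2 scale, the receptor Erbb3 was at -0.55 and -0.59, and the ectonucleotidase Nt5e was at -0.46 and -0.66. The heparan sulfate sulfotransferase Hs6st2 was at 1.63 and 0.83, the translation factor Eif4g3 at 1.75 and 0.47, and osteopontin, Spp1, at 0.26 and 0.49. The mucin Muc5ac, also chosen after its values were seen, was at 168 CPM in shMYC, 22.9 CPM in MYC WT and 28.1 CPM in MYC RBRIIIMUT (log2 -2.88 for MYC WT against shMYC, adjusted p = 4.39e-28).

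Loss of gastric-type genes beyond Muc5ac, Gkn2, Psca and Capn9 was tested on 10 other gastric foveolar genes. Of these 8 were lower in MYC WT than in shMYC and none was higher (median -0.93, adjusted p = 5.69e-06, and adjusted p = 0.00753 with an estimated correlation). In MYC RBRIIIMUT 8 were lower as well (median -0.78, adjusted p = 5.27e-06, and adjusted p = 0.00753). For MYC RBRIIIMUT against MYC WT 1 was higher, the keratin Krt20 (log2 0.23, adjusted p = 2.10e-05), and none was lower, and the list did not pass (median 0.09, adjusted p = 0.0679, and adjusted p = 0.182). MYC may hold down a gastric foveolar program in these cells, as a hypothesis found and tested on the same data, with differences between the lines left open.

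The quinone reductase Nqo1 was at 9.28 CPM in MYC RBRIIIMUT, 17.1 CPM in MYC WT and 6.01 CPM in shMYC (MYC RBRIIIMUT against MYC WT log2 -0.88, adjusted p = 2.76e-06), and the reductase Ptgr1 was also lower (log2 -0.59, adjusted p = 3.41e-04). A fall in NRF2 activity was tested on 24 other NRF2 target genes, and 2 were higher and none was lower (median 0.0269, adjusted p = 0.0303 for a rise, and adjusted p = 0.242 with an estimated correlation). The call for a rise was lost without MYC RBRIIIMUT replicate 1 (adjusted p = 0.103), without MYC WT replicate 2 (adjusted p = 0.107) and with median-of-ratios scaling (adjusted p = 0.0582), and the median stayed above 0. This argues against a fall across these 24 genes. The list does not hold every NRF2 target, and Slc7a11, lower in MYC RBRIIIMUT than in MYC WT as given above, was not among the 24. Against shMYC the list was lower in MYC WT (4 higher and 15 lower, median -0.22, adjusted p = 0.00402, and 0.182 with an estimated correlation) and in MYC RBRIIIMUT (4 and 15, median -0.17, adjusted p = 0.00591, and 0.182).

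MYC-activated core targets were lower in MYC RBRIIIMUT than in MYC WT. After all libraries were thinned to the same total of 10926300 counts the median was -0.123 (adjusted p = 1.57e-15). Under library-size and median-of-ratios scaling it was -0.123 and -0.144. TMM factors were 0.992 to 1.01, so a change of scaling could move it little. These values argue against depth and the choice of scaling as the cause. All of these settings give levels relative to the other transcripts of a library, so a difference in total mRNA per cell could not be seen. Myc counts were 0.0547 higher on the log2 scale in MYC RBRIIIMUT (-0.02 without MYC WT replicate 1), but they do not separate the endogenous gene from the construct, so a lower level of construct mRNA stays open. MYC protein was not measured here. Weaker activation by the mutant protein is a further open explanation and was not tested.

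A uniformly weaker MYC response was tested as an explanation for the list differences between MYC RBRIIIMUT and MYC WT. Of 28 lists 10 departed from the common slope with the preset correlation, 7 upward and 3 downward. With the estimated correlation as well, 4 of those upward departed. The slope was taken as fixed, without a standard error. A higher common slope could therefore also account for the departures of core targets, nucleotide synthesis and S phase. Matrix genes had medians of -0.66 with MYC WT and -0.13 with MYC RBRIIIMUT, both against shMYC. That list argues against uniform weakening, for its own genes only.

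Matrix and TGF-beta response genes were higher in MYC RBRIIIMUT than in MYC WT. Fibroblasts in the cultures were tested as a source with 15 marker genes written beforehand, whose summed CPM rose by 0.461, against 107 for the 8 called matrix genes, or 0.430%. Those matrix genes summed to 279.7 CPM in MYC RBRIIIMUT, 173 CPM in MYC WT and 322 CPM in shMYC, which argues against fibroblasts as the source. Each group was a different engineered line. The 131 genes outside the range of the other groups cannot be told apart from line differences. That explanation stays open for the matrix genes too.

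For each comparison the 6 samples have 10 splits, too few for a share under 0.05. The real split gave 1070 genes for MYC RBRIIIMUT against MYC WT and the highest other split 1. It gave 8054 for MYC WT against shMYC and 7550 for MYC RBRIIIMUT against shMYC, with 0 for the highest other split of each. Every other split mixes the groups, so a real difference between them widens the spread and few calls follow. The low counts of those splits therefore do not measure what chance gives.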
